A study of Homo sapiens with 3 samples.

How the data were processed

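Gene expression was measured on 3 arrays of long oligonucleotide probes (the human HEEBO set, printed in 48 blocks). Each array carried cDNA from prostate stromal cells (PrSC), the fibroblast-like cells of the prostate's connective tissue, in both channels. Channel 1, dye Cy5, is labelled as cells given TGFβ3 at 5 ng/mL for 24 h, and channel 2, dye Cy3, as untreated cells. The growth factor TGFβ3 signals through the TGFβ receptors and SMAD proteins. The 3 arrays form a single group. Per the labels, all 3 hybridisations are separate samples, but no label names separate cultures or extracts, so p-values measure the spread between 3 hybridisations, which may be technical. The series' design text also describes cells with a dominant-negative TGFβ receptor; those arrays were not analysed here. For RNA extraction the design text and the labels name different kits.

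The deposited scanner files hold a spot intensity per channel. In the values, the authors' image software had already subtracted the local background from the mean intensity of each spot. The deposited local background intensity and its SD stand in columns of their own. The files' own calibrated ratio, made by the authors, equals the red over the green intensity divided by 1 constant per array. The deposited spot quality is a fraction between 0 and 1, per the file headers. The deposited value table of the series holds the log2 of that calibrated ratio, with a largest difference of 5e-05. Its scale is therefore known, no gene was centred, and its medians on arrays 1, 2 and 3 were 0.0025, -0.0019 and 0.0006. The deposited log2 ratio is the column named red over the column named green. Whether red holds the treated RNA is open, as set out next, and so is whether it holds the same dye on all 3 arrays. The image software and its version are not given in the sources used here.

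The titles mark arrays 1 and 2 as reversed, the design text speaks of 1 dye swap per comparison whose data were turned to match the others, and the dye labels are the same on all 3 arrays. These statements do not agree on how many arrays were turned. By the rule fixed beforehand, the columns were read as the dye labels give them, because the correlations of the marked arrays with the unmarked array were not below the rule's limit of -0.3. Before normalization, arrays 1 and 2 had r of 0.184 and 0.235 with array 3, and rho of -0.0238 and -0.0187. For correlations above that limit the rule calls the direction unsettled. The sign is therefore that of the labels alone, and every direction below is written as higher or lower in the channel labelled TGFβ3.

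Each file held 49152 spots, of which 44206 were human probes, 4752 control spots and 194 empty spots. Spots with a quality of 0 or no area were left out, which removed 264, 269 and 401 spots from arrays 1, 2 and 3. The plan named normexp background correction with an offset of 50 for uncorrected signals; since the deposited intensity was already background-subtracted, it was used as it stood, and normexp became an alternative. Log2 ratios were normalized by loess within each array, fitted on human probes. A probe entered the test when at least 1 channel on at least 2 arrays lay 2 background SDs above the background. In all, 44035 probes were tested and 171 left out for spot quality; the filter on dim probes removed none beyond these. Each array's precision cannot be stated as counts; the number of arrays limits it. Median background-subtracted signals of the human probes on arrays 1, 2 and 3 were 367.95, 411 and 293.9 in red and 279.1, 298.1 and 555.9 in green. Empty spots had medians of 146.9, 145.15 and 97.9 in red and 97.9, 98.8 and 201.7 in green, so many tested probes lie near the level of empty spots. A stricter filter at the 95th percentile of the empty spots passed 14624 probes.

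The mean log2 ratio over the 3 arrays was tested against 0 with limma (lmFit with an intercept and eBayes), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Both RNAs were hybridised on each array, so the mean ratio against 0 is the test. No label says whether the control RNA was the same on all 3 arrays; if it was, the spread between control cultures is left out. The scanner files pair probes with Entrez gene IDs. Of the human probes, 38137 had such an ID, and 33804 of these matched a current symbol in the RefSeq gene table, used for names only. A further 4333 had an ID without a current symbol and 6069 had none. The tested probes with a symbol stood for 20316 genes. A gene was represented by its brightest tested probe, and 7722 genes had at least 2. Of these, 2 genes, DTX2 and LAMA3, had called probes in both directions.

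Genes named in the text follow a rule fixed beforehand. It takes the 12 genes per direction with the largest mean log2 ratio among those called with the same sign on all 3 arrays, 26 genes chosen for TGFβ biology, and the 4 members of each gene list with the smallest p. Some genes that these rules or the control spots would name are not reported here; counts and list tests include them. Gene lists, 19 in all, were tested with limma's camera (preset correlation 0.01), with camera on an estimated correlation and with fry, adjusted over the lists. With 3 arrays, camera on an estimated correlation has few residual degrees of freedom, so missing it does not show that a list was unshifted. These list tests used members measured on all 3 arrays; counts of members use every tested member. Counts adjusted over a list alone use only its members' p-values.

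The procedure was tested on simulated arrays for this comparison, with 200 of 43760 probes changed. Without a dye term, 85.1% of probes changed by 1 on the log2 scale were recovered, 100% of those changed by 2 and 0% of those changed by 0.5, with 0% false calls. The data gave 1438 called probes, and with fewer changed probes the adjusted threshold is stricter. The recovery of small changes in the simulation therefore does not carry over to the data. With a dye term, 62.7% of probes changed by 0.5 were recovered and 11.2% of calls were false. Alternatives covered the background correction, the normalization, the authors' values, the filter on dim probes, saturated spots, the orientation of the marked arrays, a dye term per probe, leaving out each array, and the prior of eBayes. The scanner software's own ratio is the same quantity as the value table and gave no separate alternative. R 4.3.3 with limma 3.58.1 was used, and figures were drawn with matplotlib 3.10.9.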

Results

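Expression in prostate stromal cells was compared between a channel labelled as treated with TGFβ3 (5 ng/mL, 24 h) and a channel labelled as untreated, on 3 arrays. The comparison asks which stromal genes respond to TGFβ3, in a study concerned with stromal genes of tissue remodelling. Of 44035 tested probes, 1438 passed limma's test at an adjusted p under 0.05. All ratios are given as the channel labelled TGFβ3 over the channel labelled control, on the log2 scale, as mean ± SD over the 3 arrays.

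By these labels, 9 of 18 TGFβ feedback and early target genes and 15 of 32 matrix protein genes were lower in the channel labelled TGFβ3. Both lists passed camera's test with a preset correlation and fry (adjusted p = 0.0156 and 0.00993 by fry), but not camera with an estimated correlation (adjusted p = 0.181 each). IGFBP3, an insulin-like growth factor binding protein, had a log2 ratio of -3.48 ± 0.24 (n = 3), a fold of 11.2, and TIMP3, an inhibitor of metalloproteinases, one of -3.19 ± 0.01. The other TIMP3 probe was also lower (-1.85 ± 0.10). HGF had a log2 ratio of 2.61 ± 0.23, a fold of 6.10. This direction is opposite to the study's, whose title describes upregulation of remodelling genes by TGFβ, and the labels conflict on which arrays were turned, so the direction is unsettled. With the sign turned on all 3 arrays, the genes given here as lower become those raised under TGFβ3, and the reverse; sizes, p-values and counts stay as they are.

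By their brightest probe, 213 genes were higher and 559 lower in the channel labelled TGFβ3, of 20316 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 56 were at least 2-fold higher and 124 at least 2-fold lower. After HGF, the largest positive ratios were those of TCF21, a transcription factor of mesenchymal cells (2.52 ± 0.34), the monocyte chemokine CCL2 (2.25 ± 0.21), the matrix protease ADAMTS1 (2.18 ± 0.27) and the plasminogen activator PLAT (2.02 ± 0.41; 1 of its 3 spots lay near the scanner's full scale). SMPDL3A (2.01 ± 0.22), HSD17B2, which oxidises sex steroids (1.89 ± 0.25), AKR1C1, an aldo-keto reductase (1.89 ± 0.11), STOM (1.76 ± 0.68), the retinol dehydrogenase RDH10 (1.73 ± 0.14), TM4SF1 (1.72 ± 0.11) and the adhesion molecule VCAM1 (1.66 ± 0.62) followed. The adjusted p of these 12 genes ranged from 0.000206 to 0.0112. Of the 3 AKR1C1 probes, 2 were called higher and the other had a log2 ratio of -0.10 (adjusted p = 0.674). ADAMTS1 was called by 1 of its 2 probes, and the other had a log2 ratio of 0.86 (limma adjusted p = 0.283).

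Large negative ratios besides IGFBP3 and TIMP3 were those of TSPAN13 (-2.95 ± 0.33), the cadherin CDH6 (-2.91 ± 0.17), the activin subunit INHBA (-2.89 ± 0.36), LRRC17 (-2.64 ± 0.27) and the cytokine IL33 (-2.50 ± 0.19). APCDD1L (-2.45 ± 0.39), MS4A1 (-2.41 ± 0.31), the collagenase MMP1 (-2.27 ± 0.53) and CCDC39 (-2.14 ± 0.08) followed. The adjusted p of these 11 genes ranged from 0.000101 to 0.00186. MS4A1 encodes a B-cell surface protein and was measured by 1 probe. CCDC39 was called by 1 of its 3 probes, and the highest of the 3 had a log2 ratio of -0.000873.

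**Figure D1:**
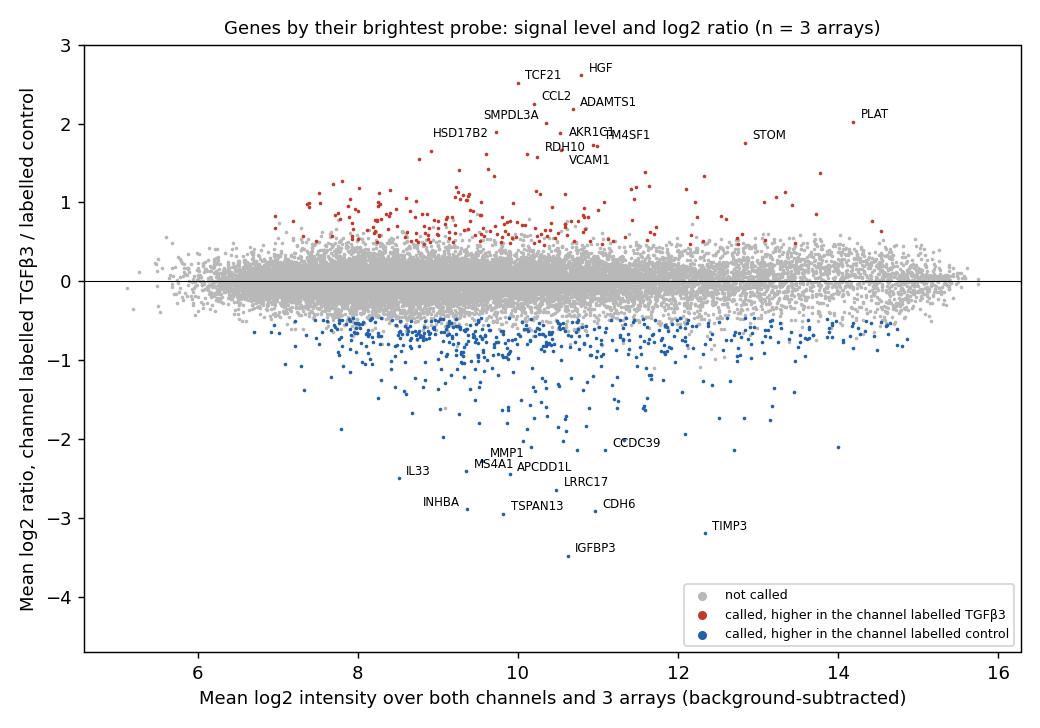
Each point is a gene by its brightest probe, with the mean log2 intensity over both channels on the horizontal axis and the mean log2 ratio of 3 arrays (channel labelled TGFβ3 over channel labelled control) on the vertical axis. Coloured points passed an adjusted p of 0.05, and the genes with the largest ratios that the text reports are named, from HGF at 2.61 to IGFBP3 at -3.48.

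Of 18 tested genes of the TGFβ pathway's own feedback and early response, 9 were lower in the channel labelled TGFβ3, 0 were higher and 9 did not pass (12 lower and 0 higher adjusted over the list alone). The list had a median log2 ratio of -0.55 and a camera adjusted p of 4.01e-13. The adjusted p was 0.181 with an estimated correlation and 0.0156 by fry. Among the lower members were CCN2, a matricellular growth factor (-1.63 ± 0.08), the type I receptor TGFBR1 (-1.09 ± 0.14), the ligand TGFB1 (-1.02 ± 0.09), the SMAD repressor SKIL (-1.11 ± 0.16), TGFBI (-0.87 ± 0.19) and the inhibitory SMAD7 (-0.71 ± 0.23). SMAD7 was not above the level of empty spots. Among 14 targets of the related BMP pathway, 1 was higher, 0 were lower and 13 did not pass (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.577). ID2 was the member called (0.70 ± 0.13, near the level of empty spots, by 1 of its 2 probes), and ID1 had 0.12 ± 0.22 with an adjusted p of 0.697.

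The list of collagens and other matrix proteins lay lower in the channel labelled TGFβ3 by camera's preset correlation (adjusted p = 7.74e-08) and by fry (adjusted p = 0.00993). It did not pass camera with an estimated correlation (adjusted p = 0.181). Of 32 tested, 15 were lower, 3 higher and 14 did not pass (18 lower and 3 higher adjusted over the list alone). Elastin, ELN, had a log2 ratio of -1.35 ± 0.14, COL11A1 of -1.37 ± 0.16, COL5A1 of -1.26 ± 0.05, COL4A1 of -0.87 ± 0.37, fibronectin, FN1, of -0.82 ± 0.33 and COL1A1 of -0.77 ± 0.17. The fibrillin FBN2 was higher (0.99 ± 0.17), as were the small proteoglycans DCN (0.60 ± 0.13, called by 1 of its 3 probes) and LUM (0.59 ± 0.20, near the level of empty spots). For COL11A1, 1 of 3 probes was called, and the highest had a log2 ratio of 0.09. Tenascin C, TNC, was lower by all 8 of its probes: the brightest gave -0.60 ± 0.15, and all others lay between -2.22 and -2.85. Of 6 FN1 probes, 5 were lower.

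Enzymes that modify and crosslink collagen lay lower as a list, with 2 of 16 called lower and 14 not passing (8 lower and 0 higher adjusted over the list alone). The camera adjusted p was 1.63e-05, and the adjusted p was 0.181 with an estimated correlation and 0.0156 by fry. The lysyl hydroxylase PLOD2 had a log2 ratio of -1.40 ± 0.04 and the lysyl oxidase LOX one of -0.64 ± 0.09. Of the 3 PLOD2 probes, 2 were called lower and the other had a log2 ratio of 0.04 (adjusted p = 0.894). P4HA1, a subunit of prolyl hydroxylase, missed the threshold by its brightest probe (-0.46 ± 0.07, adjusted p = 0.0505), while 3 of its 4 probes were called lower.

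Of 20 contractile genes of smooth muscle and myofibroblasts, 5 were lower, 1 was higher and 14 did not pass (8 lower and 1 higher adjusted over the list alone). The smooth muscle actin ACTG2 (-1.73 ± 0.11), the actin-bundling protein PALLD (-1.70 ± 0.13), tropomyosin TPM1 (-1.58 ± 0.07) and transgelin, TAGLN (-1.40 ± 0.38) were among the lower genes. The list had a camera adjusted p of 7.13e-05, and an adjusted p of 0.201 with an estimated correlation and 0.0194 by fry. For α-smooth muscle actin, ACTA2, the probes differed. The brightest gave 0.14 ± 0.36 (adjusted p = 0.72), with 1 of its 3 spots near the scanner's full scale, and the other gave -2.30 ± 0.15 (adjusted p = 0.000206). Calponin, CNN1, was not called by any of its 3 probes (brightest -0.18 ± 0.13, adjusted p = 0.459, with 1 of its 3 spots near full scale). The other CNN1 probes gave -0.71 ± 0.63 and -0.52 ± 0.38, with adjusted p of 0.174 and 0.149. Of 5 TPM1 probes, 3 were lower.

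Matrix proteases and their inhibitors changed in both directions, with 9 of 22 lower, 3 higher and 10 not passing (11 lower and 3 higher adjusted over the list alone). Besides TIMP3 and MMP1, the protease inhibitor SERPINE2 was lower (-2.09 ± 0.38), while PLAT and ADAMTS1 were higher. The list as a whole lay lower, with a camera adjusted p of 7.13e-05. The adjusted p was 0.186 with an estimated correlation and 0.0194 by fry. MMP2, a gelatinase, had -0.28 ± 0.41 and did not pass (adjusted p = 0.478).

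**Figure D2:**
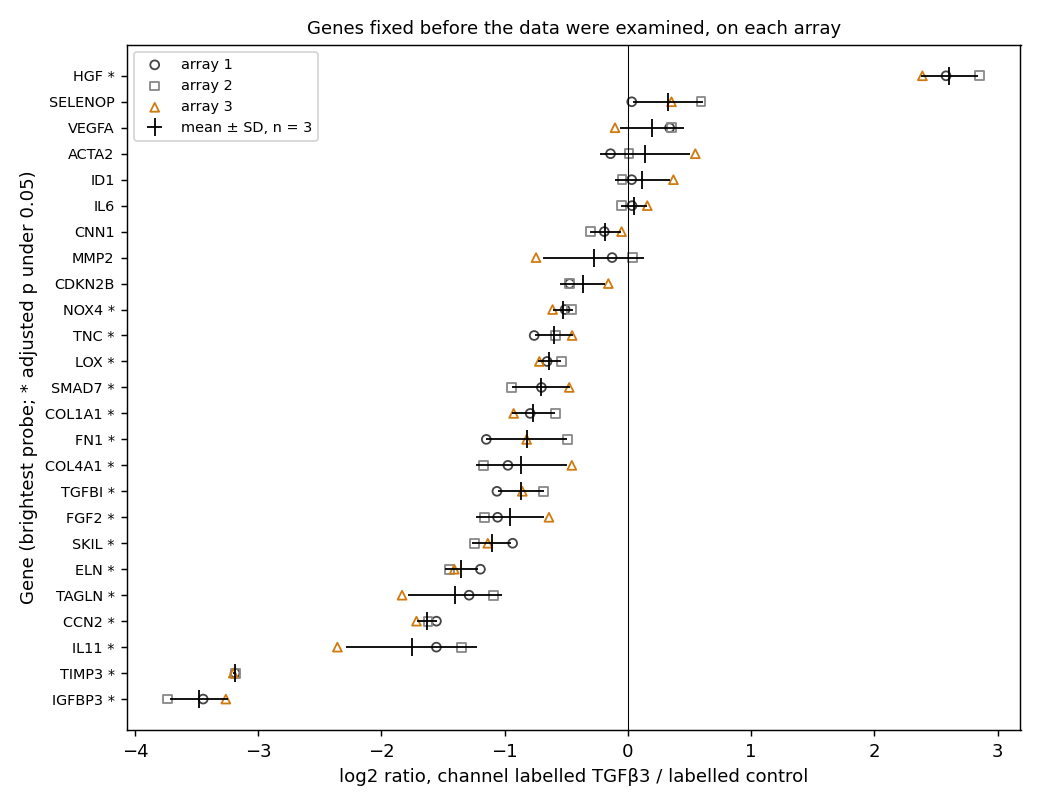
Log2 ratios (channel labelled TGFβ3 over channel labelled control) of genes chosen before the data were examined, with a symbol per array, a bar for the mean and a line for the SD (n = 3). HGF lies at 2.61, and IGFBP3 and TIMP3 lie at -3.48 and -3.19.

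Among 27 secreted growth factors and their binding proteins, 5 were higher, 6 lower and 16 did not pass (6 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.559). The epidermal growth factor family member AREG (-1.68 ± 0.23) and FGF2 (-0.95 ± 0.28) were lower with IGFBP3 and INHBA, and HGF was higher. VEGFA had 0.20 ± 0.26 and did not pass (adjusted p = 0.52). Among 23 cytokines and chemokines, 6 were higher, 4 lower and 13 did not pass (7 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.327). CCL2 and the neutrophil chemokine CXCL3 (0.95 ± 0.10, called by 1 of its 2 probes) were higher, and IL33 and IL11 (-1.75 ± 0.53) were lower. IL6 had 0.05 ± 0.10 near the level of empty spots (adjusted p = 0.873).

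The list of redox genes lay higher in the channel labelled TGFβ3 by camera's preset correlation (adjusted p = 2.43e-06) and by fry (adjusted p = 0.0194). It did not pass camera with an estimated correlation (adjusted p = 0.181). Of 17 tested, 4 were higher, 1 was lower and 12 did not pass (7 higher and 1 lower adjusted over the list alone). The mitochondrial superoxide dismutase SOD2 (1.61 ± 0.33), the quinone reductase NQO1 (1.17 ± 0.17), thioredoxin, TXN (0.83 ± 0.08) and its reductase TXNRD1 (0.69 ± 0.11) were higher, and the superoxide-producing oxidase NOX4 was lower (-0.53 ± 0.08). NOX4 was called by 1 of its 2 probes, and the other had a log2 ratio of -0.41 (limma adjusted p = 0.348). SELENOP, a plasma selenoprotein, had 0.33 ± 0.28 and did not pass (adjusted p = 0.294).

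The list of endoplasmic reticulum chaperones lay lower by camera's preset correlation (adjusted p = 1.81e-05) and by fry (adjusted p = 0.0192). It did not pass camera with an estimated correlation (adjusted p = 0.186). Of 16 tested, 4 were lower and 12 did not pass (9 lower and 0 higher adjusted over the list alone). DNAJB9 (-0.89 ± 0.14), PDIA6 (-0.63 ± 0.07), HSP90B1 (-0.57 ± 0.10) and HERPUD1 (-0.47 ± 0.08) were the members called, DNAJB9 and HERPUD1 near the level of empty spots and HSP90B1 by 1 of its 4 probes. Of 12 genes of cholesterol synthesis, the squalene epoxidase SQLE was lower (-0.71 ± 0.11), 0 were higher and 11 did not pass (3 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.0778). None of 17 ribosomal protein genes passed singly in limma's test, while 4 had an unadjusted p under 0.05 (2 higher and 0 lower adjusted over the list alone). Their list median of 0.18 had a camera adjusted p of 0.000179, but an adjusted p of 0.646 with an estimated correlation and 0.284 by fry.

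Calls were few among genes of cell division, as over all tested genes, of which 3.80% were called. Above the level of empty spots lay 8 of the 26 members. Of 26, 1 was higher (CDC20, 0.55 ± 0.05), 1 was lower (CCNA2, -0.82 ± 0.25, near the level of empty spots) and 24 did not pass (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.723). CDC20 was called by 1 of its 2 probes, and the other had a log2 ratio of 0.21 (limma adjusted p = 0.37). None of 10 genes of growth arrest passed in limma's test, over all probes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.723). The cell cycle inhibitor CDKN2B had -0.37 ± 0.18 by its brightest probe (adjusted p = 0.156), while another of its 4 probes was called at -1.12. Of 16 interferon response genes, 2 were higher, 0 lower and 14 did not pass (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.214). These were IFIT1 (0.74 ± 0.34, near the level of empty spots) and IRF1 (0.46 ± 0.04, called by 2 of its 4 probes). With the mean over a gene's probes, the interferon list passed, with a camera adjusted p of 0.0324, but not with an estimated correlation (adjusted p = 0.325, and 0.488 by the brightest probes). Members of the fixed marker lists of other cell types were not called by limma: 0 of 12 epithelial, 0 of 8 endothelial, 0 of 9 leukocyte and 0 of 6 neural genes passed, over all probes or adjusted over the list alone. Of these, 1 endothelial gene, CLDN5 (0.27 ± 0.12), had an unadjusted p under 0.05. Above the level of empty spots lay 8 of the epithelial, 3 of the endothelial, 1 of the leukocyte and 3 of the neural genes. For the dim members, a missing call says little. Outside these lists, the B-cell gene MS4A1 was lower (-2.41), as were the leukocyte genes TREM1 (-2.10) and GZMB (-2.03), both named after their values were seen. The 4 lists had camera adjusted p of 0.586, 0.696, 0.466 and 0.718.

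**Figure D3:**
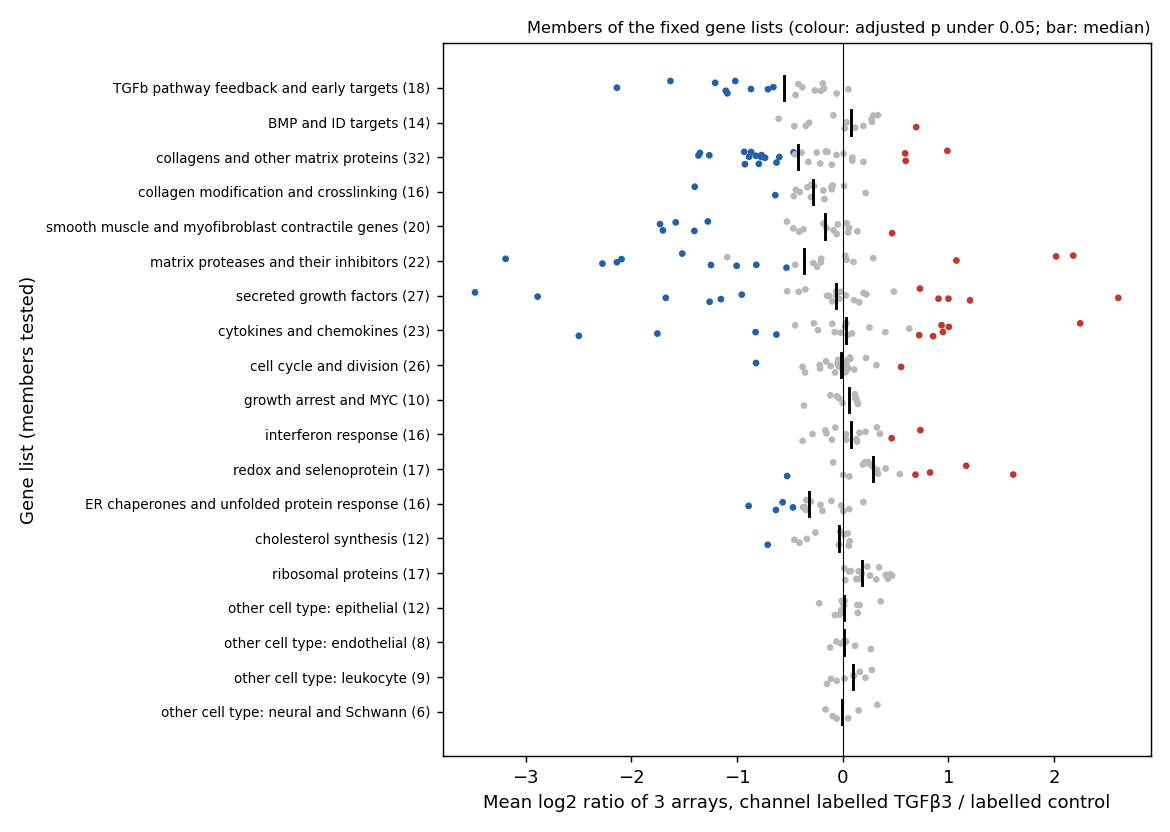
Each point is a tested member of a gene list, placed by its mean log2 ratio of 3 arrays (channel labelled TGFβ3 over channel labelled control); coloured points passed an adjusted p of 0.05 and the bar is the list's median. The TGFβ target list has 9 members called lower and 0 called higher.

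The 3 arrays did not agree equally well. Across the tested probes, which are not independent replicates, arrays 1 and 2 correlated with r = 0.753 (rho = 0.697), arrays 1 and 3 with r = 0.231 (rho = 0.0112) and arrays 2 and 3 with r = 0.274 (rho = 0.00715). Over the 10439 probes with a mean log2 intensity above 10, r was 0.911, 0.392 and 0.422. Counts of called genes depended on array 3 and array 2: leaving out array 3 gave 2148 higher and 2531 lower genes, and leaving out array 2 gave 96 and 208. Without array 3, both arrays left are marked as reversed, so a dye effect that they share cannot be told from a response. Of the genes called there, 54.1% were lower, against 72.4% with all 3 arrays. The median SD between arrays was between 0.155 and 0.218 in 4 classes of signal intensity.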

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

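The comparison of control spots was chosen after the results were seen. Besides the human probes, the arrays carry many control spots of common genes, which entered no comparison. For 4 genes reported here the ratio had the same sign on all 3 arrays and lay beyond 0.322 on the log2 scale, the size that 95 in 100 probes for bacterial and archaeal spike transcripts did not exceed. In the channel labelled TGFβ3, the median log2 ratio of the control spots was -0.35 ± 0.13 for the cytoskeletal actin ACTB (438 spots) and -0.38 ± 0.11 for the retinoblastoma gene RB1 (48 spots). It was 0.43 ± 0.15 for B2M, the light chain of MHC class I (48 spots), and 0.52 ± 0.30 for the ribosomal protein gene RPL13A (48 spots), as mean ± SD of 3 arrays. No test was run on these values.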

How the results depend on the processing

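Alternatives were fixed before the data were examined, except normexp with an offset of 50 and the filter at the level of empty spots, which were chosen after the data were seen. Apart from turning the marked arrays, 1674 values of the 106 named genes were recomputed. Of these, 1571 kept their direction and side of the threshold, 59 lost the call, 44 gained it and 0 changed direction where a call was involved. HERPUD1 lost its call most often, under 8 alternatives, followed by TNC and IRF1 under 7 each. The median of the TGFβ target list stayed between -0.67 and -0.34. The planned filter on dim probes removed none, so leaving it off says nothing about stability. Signal over background limits the dimmest genes: above the level of empty spots, 8498 genes could be tested. The test of the ratio within each array is already a paired one, so pairing gave no further alternative.

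Besides turning the marked arrays, 5 kinds of alternative moved counts by over 1.5 times. Without background correction, genes at least 2-fold higher and lower numbered 23 and 73. Print-block loess gave 720 probes and 339 genes called higher. With a dye term per probe, 1488 probes were higher and 2403 lower, and 686 genes higher and 1329 lower. That fit leaves 1 residual degree of freedom and made false calls in the simulation. With a trended, robust prior, 177 probes were higher and 564 lower, and 87 genes higher and 323 lower. Leaving out 1 array gave between 194 and 4489 probes higher and between 368 and 4845 lower. For genes it gave between 96 and 2148 higher and between 208 and 2531 lower. Genes at least 2-fold higher numbered between 47 and 86, and at least 2-fold lower between 108 and 176. The highest counts came without array 3, which leaves only the marked arrays, and the lowest without array 2. A dye effect shared by the marked arrays cannot be told from a response when array 3 is left out. Beyond these constructions the cause was not tested.

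For gene lists, the call was lost with an estimated correlation for TGFβ targets, matrix proteins, collagen modification and redox genes (adjusted p = 0.181 each), proteases and endoplasmic reticulum chaperones (adjusted p = 0.186 each), contractile genes (adjusted p = 0.201) and ribosomal proteins (adjusted p = 0.646). By fry, ribosomal proteins lost it too (adjusted p = 0.284), while the other lists just named kept it (adjusted p from 0.00993 to 0.0194). The interferon list passed with the mean over probes (median 0.13), but not with an estimated correlation there (adjusted p = 0.325). Cholesterol synthesis passed with print-block loess (median -0.073) and above the level of empty spots (median -0.30). With an estimated correlation it passed in neither (adjusted p = 0.626 and 0.563), nor in the main setting (adjusted p = 0.444). The estimated correlations of TGFβ targets, matrix proteins, collagen modification and redox genes were -0.0214, -0.0307, -0.0490 and -0.0486, below the preset 0.01. A stronger correlation among members therefore does not account for these lost calls. For the other lists that lost a call, the estimated correlation ranged from 0.0190 to 0.675. Beyond this the cause was not tested.

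Turning the marked arrays ended every call of the count tests: limma called 0 probes and 0 genes higher or lower, and 0 at least 2-fold either way, with 2740 probes higher and 3590 lower at an unadjusted p under 0.05. Directions reversed because 2 of the 3 arrays then carry the other sign. In the main setting, 100% of the called probes had the same sign on all 3 arrays. For the genes called there, the turned means below therefore average ratios of opposed sign, and are not to be read as sizes of a response. List medians became 0.32 for TGFβ targets, 0.20 for matrix proteins, 0.11 for collagen modification, 0.21 for contractile genes, 0.30 for proteases, -0.17 for redox genes, 0.0942 for endoplasmic reticulum chaperones and -0.23 for ribosomal proteins. By camera's preset correlation only ribosomal proteins still passed, now lower (adjusted p = 0.000608, and 0.926 with an estimated correlation). The adjusted p of the others by the preset ranged from 0.0699 for TGFβ targets to 0.387. Among the 106 named genes, those called in the main setting whose log2 ratio turned negative were HGF -1.02, TCF21 -1.10, CCL2 -0.61, ADAMTS1 -0.90, PLAT -0.89, SMPDL3A -0.53, HSD17B2 -0.82, AKR1C1 -0.60, STOM -1.08, RDH10 -0.66, TM4SF1 -0.49, VCAM1 -0.92, ID2 -0.17, FBN2 -0.38, CXCL3 -0.27, CDC20 -0.15, IFIT1 -0.47, IRF1 -0.14, SOD2 -0.79, NQO1 -0.49, TXN -0.23, TXNRD1 -0.25. Those called in the main setting whose log2 ratio turned positive were IGFBP3 1.31, TIMP3 1.06, TSPAN13 1.20, CDH6 1.04, INHBA 1.20, LRRC17 1.09, IL33 0.96, APCDD1L 1.09, MS4A1 0.80, MMP1 1.15, CCDC39 0.68, TGFBI 0.30, CCN2 0.49, SMAD7 0.39, SKIL 0.35, TAGLN 0.18, COL1A1 0.15, COL4A1 0.56, FN1 0.27, TNC 0.30, ELN 0.41, LOX 0.16, FGF2 0.53, IL11 0.18, NOX4 0.12, TGFBR1 0.26, TGFB1 0.39, COL5A1 0.38, COL11A1 0.45, PLOD2 0.50, ACTG2 0.66, PALLD 0.51, TPM1 0.51, SERPINE2 0.57, AREG 0.72, CCNA2 0.44, DNAJB9 0.32, PDIA6 0.26, HSP90B1 0.27, HERPUD1 0.19, SQLE 0.32.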

Other observations

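Except for the checks of array 3 and of probes for alternative exons, the tests here were chosen after the results were seen, and the genes in the next sentences were picked from their values. Receptors and signalling genes were among those higher in the channel labelled TGFβ3: the PDGF receptor PDGFRA (1.20 ± 0.26), the interleukin-1 receptor IL1R1 (1.65 ± 0.19), the hypoxia factor EPAS1 (1.58 ± 0.23), the guidance ligand SLIT2 (1.41 ± 0.28), the decoy receptor TNFRSF11B (1.61 ± 0.19) and SMAD3, a signal transducer of the TGFβ receptor (0.90 ± 0.40). The lysosomal protease CTSC was higher by all 8 of its probes. Lower were the skeletal muscle actin ACTA1 (-1.94 ± 0.09), the calcification inhibitor MGP (-1.75 ± 0.07), the ligand PDGFD (-1.80 ± 0.08) and the metalloprotease ADAM12, called lower by 7 of 8 probes. All were called by limma at an adjusted p under 0.05, and the open direction of the arrays holds for them too.

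HSD17B2, AKR1C1 and RDH10 among the largest positive ratios prompted a count over the families of aldo-keto reductases, of retinoid and steroid dehydrogenases and of the retinoid hydroxylases CYP26. Of 53 tested protein-coding members, 9 were higher and 1 lower, with a median log2 ratio of 0.07. AKR1C2 (1.20), ALDH1A1 (0.92) and AKR1C3 (0.87) were among the higher ones, ALDH1A1 and AKR1C3 near the level of empty spots. Without the 3 genes that prompted the count, 6 of 50 members were higher and 1 lower, with a camera p of 0.0307, and 0.119 with an estimated correlation. The 6 include AKR1C2 and AKR1C3, close relatives of AKR1C1 whose probes may share its signal. The members left are thus not independent of the genes that prompted the count. The members were first taken by symbol prefix, which brought in other enzymes, pseudogenes and antisense RNAs, and were corrected after that result was seen. By prefix, the camera p was 0.0104 with all 62 members and 0.117 without the 3 (0.12 and 0.278 with an estimated correlation). Since the p depends on the choice of members and of correlation, a coordinated shift of the families stays an open hypothesis. Of 11 IFITM genes and pseudogenes, 5 were higher: IFITM1 (1.03), IFITM2 (0.96), IFITM3 (0.85), IFITM3P2 (1.07) and IFITM4P (1.01). These are close copies of each other, so their probes may share signal. Whether they belong to a wider interferon response stays open: the fixed interferon list had an adjusted camera p of 0.214 (0.488 with an estimated correlation), and with the mean over probes it passed at 0.0324 but not with an estimated correlation (0.325).

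The TGFβ target list lay lower in the channel labelled TGFβ3 by camera's preset correlation and by fry (adjusted p = 0.0156), though not with an estimated correlation (adjusted p = 0.181). This is the opposite of what this pathway's feedback genes are known to do under TGFβ. With a dye term per probe, set by the titles' marks, the list's median remained at -0.51. This argues against a dye effect specific to each gene only if the marks give the dye order. With the same dye order on all 3 arrays, as the dye labels give it, the fit could not separate such an effect from a response. An exchange of the deposited channel columns relative to the labels would give this pattern, and so would a true decrease under TGFβ3, with the list's median below 0 on all 3 arrays (-0.62, -0.61 and -0.47). The exchange and the true decrease cannot be told apart here, because both predict the same values. Since the median had the same sign on all 3 arrays, only an exchange on all 3 would account for it. Turning the marked arrays alone would set them against array 3.

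Array 3 correlated weakly with arrays 1 and 2 over all probes (r = 0.231 and 0.274). Lower measurement quality of array 3 is argued against, since the SD between copies of control probes was 1.03 times the mean of arrays 1 and 2. A dye effect specific to each probe, with array 3 of the other dye order, may account for it. Over 1616 probes for bacterial and archaeal spike transcripts, which carry no response of the cells, arrays 1 and 3 correlated with r = -0.232 and arrays 2 and 3 with r = -0.264, against r = 0.483 for arrays 1 and 2. Median local background in red was 276 and 267.3 on arrays 1 and 2 and 290.4 on array 3, and in green 298.1, 293 and 264.9. The median SD of that background in red was 8.6 and 7.6 on arrays 1 and 2 and 3.4 on array 3. In green it was 4.3, 3.6 and 7.5. By this SD, red on array 3 resembled green on arrays 1 and 2, as columns exchanged on 1 side of a dye swap would give. No biological explanation was tested, as the design gives none.

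Probes were compared with at least 2 other probes of the gene above a mean log2 intensity of 9. Genes with dimmer companions, such as CCDC39, were left out. Some probes changed at least 2-fold while the median of these companions moved by under 0.25 of that change. All 17 such probes, of 16 genes, were lower in the channel labelled TGFβ3: 17 of 54 lower probes with enough companions against 0 of 53 higher ones, a difference not tested apart from the data that showed it. TAPBP, called lower by 1 of its 6 probes at -1.73, is an example. Carry-over from the spot printed to the left may explain part: 17.6% (exact 95% interval 3.80 to 43.4) had a left neighbour called lower, such as FN1 beside WDFY3 and SYNE2, against 2.53% of changed probes of both directions whose companions moved too and 3.33% of the lower ones. Probes for alternative exons were 1.16 times as frequent among the 17 as among changed probes of both directions whose companions moved (70.6% against 60.8%, or 63.3% of the lower ones), so splicing stays open as well, and neither share decides.

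Because a single group of arrays has no labels to exchange, the sign of each array was turned instead. With the signs as labelled limma called 1438 probes, and 1 of the 4 choices of sign gave as many; the highest of the other choices gave 0 called probes, with 138, 134 and 6330 at an unadjusted p under 0.05 when array 1, 2 or 3 was turned. Choices of sign this few cannot give a share under 0.05.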
